A study of Homo sapiens with 4 samples.

How the data were processed

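Chromatin contacts were measured by BL-Hi-C in 4 libraries of HepG2, an established human hepatocellular carcinoma line: 2 libraries labelled control and 2 labelled as a knockdown of RBM25, an RNA-binding protein of the spliceosome. Per the labels' protocols, cells were fixed with formaldehyde, nuclei were digested with HaeIII, and proximity ligation was done with a biotinylated bridge linker, so that ligated fragments could be pulled down with streptavidin. Groups and replicate numbers came from the sample titles. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

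The authors deposited 1 table of anchor pairs per library. Per the file headers, each row holds 2 anchors with their positions, the counts at each anchor and the count of paired-end tags (PETs) that join them; these deposited counts are whole numbers and were not normalised. Per the file headers each pair also has a false discovery rate, a p-value-like measure from the authors' model, which was used here only to choose pairs within a library. HiC-Pro and the builds GRCh37 and hg19 are named in the submitters' processing notes, with no version or role. The peak caller, duplicate removal and model settings are not given in the sources used here. Anchors carry numbers of their own in each library, and their number differed between libraries, so a sum over anchors moves with how much of the genome was called. All coordinates are hg19, counted from 1.

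Anchors of chromosomes 1 to 22 and X were used, and mitochondrial anchors were counted apart. Anchors that overlapped by 1 bp or more across libraries were merged into 593939 regions with a median width of 1688 bp, of which 56.5% held an anchor of all 4 libraries. A loop was a pair of merged anchors 20 kb or more apart that was called at a false discovery rate under 0.05 with 2 or more PETs in both libraries of at least 1 group. There were 468264 such loops, and edgeR's filterByExpr with a minimum count of 10 kept 42200. Bin pairs were intrachromosomal pairs of different 100 kb bins up to 10 Mb apart with a mean count of 10 or more, which kept 132044 of 1716781. Interchromosomal PETs were summed over 253 chromosome pairs. Values printed for a loop or bin pair were scaled to 1000000 intrachromosomal PETs of the library.

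Loops, bin pairs and chromosome pairs were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM factors for loops and bin pairs and library size for chromosome pairs, and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Compartments came from the first principal component of the correlation matrix of observed over expected PETs in 1 Mb bins, computed per chromosome after centring the columns, turned so that bins with more anchors were positive (A) and scaled to an SD of 1. On chromosomes 13, 16, 17 and 22 the eigenvector followed anchor density weakly, with r from 0.0439 to 0.320 against 0.418 to 0.894 on the others, so B there need not be the class with few anchors. Bins under 0.1 of the chromosome's median coverage were left out. The matrices were not corrected for the totals of the bins, so the classes A and B can follow coverage. Compartment strength was the sum of the mean observed over expected values of A with A and B with B bins, divided by that of A with B bins. Insulation was the log2 of the PETs that cross a 50 kb bin within 500 kb, over the chromosome mean, for bins with a mean of 1 PET or more per cell of the square. Both were tested with limma 3.58.1. Single values per library were compared with an exact two-sided permutation test over the 6 ways to choose 2 of 4 libraries, whose smallest p is 0.333. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

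The loops and bin pairs named were fixed by a rule before the data were examined: the 5 with the smallest p in each direction whose log-CPM in both knockdown libraries lay on the same side of both controls, given as not passing where none passed. The alternatives were DESeq2 1.42.0, its size factors, library size alone, loess offsets, no filter on low counts, the replicate number as a block, each library left out, and other bins, distances, PET minimums and windows. Offsets for region totals, anchors present in all 4 libraries, balanced matrices, a run without chromosomes 13, 16, 17 and 22, and edgeR on the PET sums behind insulation were added after seeing the data. For a bin pair the offset was the sum of the logs of both regions' totals, the tested pair included. Where all contacts of both regions rise alike, it subtracts more than the rise, so a change of sign can follow from the correction.

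Tests of loops, bin pairs, compartments and insulation were run on simulated data with 200 changed features. The test of chromosome pairs was run with 25 changed at each fold, with TMM factors. edgeR recovered 6% of loops changed 2-fold and 60% of those changed 4-fold, with 3 false calls among 42200. For bin pairs it recovered 24% and 82%, with 3 false calls among 132044. For chromosome pairs it recovered 100% at both folds, with 0 false calls among 253. limma recovered 25% of compartment bins shifted by 0.5 and 65% of those shifted by 1, among 2597 bins, with 5 false calls. For insulation it recovered 0% at both shifts among 39625 bins, so a count of 0 by limma there carries little information. edgeR on the PET sums behind insulation recovered 92% of bins changed 2-fold and 100% of those changed 4-fold, with 8 false calls. Simulated features varied independently, without the overlap of insulation windows or deviations shared across a library. Recovery in the real libraries may therefore be lower, and a count of 0 by edgeR does not exclude changes. The simulated compartment classes were all recovered, 100% of 150 bins. That simulation had even coverage, enriched A with A and B with B bins alike, and was scored with the better of the 2 signs. It therefore does not show how well classes were recovered in these libraries.

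The design fixed beforehand also held contacts of promoters, gene lists and loop classes by promoter, YY1 and CTCF sequence. These need a genome and gene positions of hg19, which were not used here, so regions are given by coordinates and not by genes. Whether RBM25 was depleted was not analysed here, since the assay reads genomic DNA.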

Results

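The 4 BL-Hi-C libraries of HepG2 addressed how chromatin structure depends on RBM25. They held 18794598 and 20163664 PETs in the control libraries and 22931672 and 18394469 in the knockdown libraries. Intrachromosomal PETs numbered 16073584 and 17134590 in controls and 19426149 and 15517830 in knockdown libraries. The authors' tables listed 470287 and 529579 anchors in controls and 551456 and 547709 in knockdown libraries, covering 929 and 1068 Mb against 1126 and 1070 Mb. Pairs joined by a single PET made up 80.1% ± 0.156 of intrachromosomal pairs in controls and 80.0% ± 0.691 in knockdown libraries (SD, n = 2 each). A chi-square test over chromosomes gave 9.4 per degree of freedom between the knockdown libraries and 1530 between the controls. It gave 258 and 211 between control replicate 2 and knockdown replicates 1 and 2, and 2848 and 2459 for control replicate 1, so control replicate 2 lay closer to the knockdown libraries than to the other control, and each pair of libraries differed by more than sampling noise. The test takes PETs as independent, and duplicates that may remain and anchors called per library also raise it, so it does not show that the libraries are separate samples.

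Contacts over 20 to 100 kb took a larger share of PETs in both knockdown libraries than in either control. Among intrachromosomal PETs of 20 kb or more, this class made up 30.2% ± 0.0886 in knockdown libraries and 29.3% ± 0.135 in controls (SD, n = 2 each). Contacts over 100 kb to 1 Mb made up 42.3% ± 0.0103 against 42.8% ± 0.153, and those over 1 to 10 Mb 16.1% ± 0.0678 against 16.5% ± 0.0937. Contacts over more than 10 Mb overlapped between groups, at 11.3% ± 0.0310 and 11.4% ± 0.195. The first 3 classes each gave an exact permutation p of 0.333, the smallest that 2 against 2 libraries allow. With only pairs of 2 or more PETs, on the same base of 20 kb or more, the 20 to 100 kb class made up 56.6% ± 0.972 in knockdown libraries and 55.5% ± 1.15 in controls, and the groups overlapped. For these pairs the 1 to 10 Mb class made up 2.24% ± 0.192 against 2.56% ± 0.215, without overlap (exact permutation p = 0.333). The other classes overlapped.

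**Figure D1:**
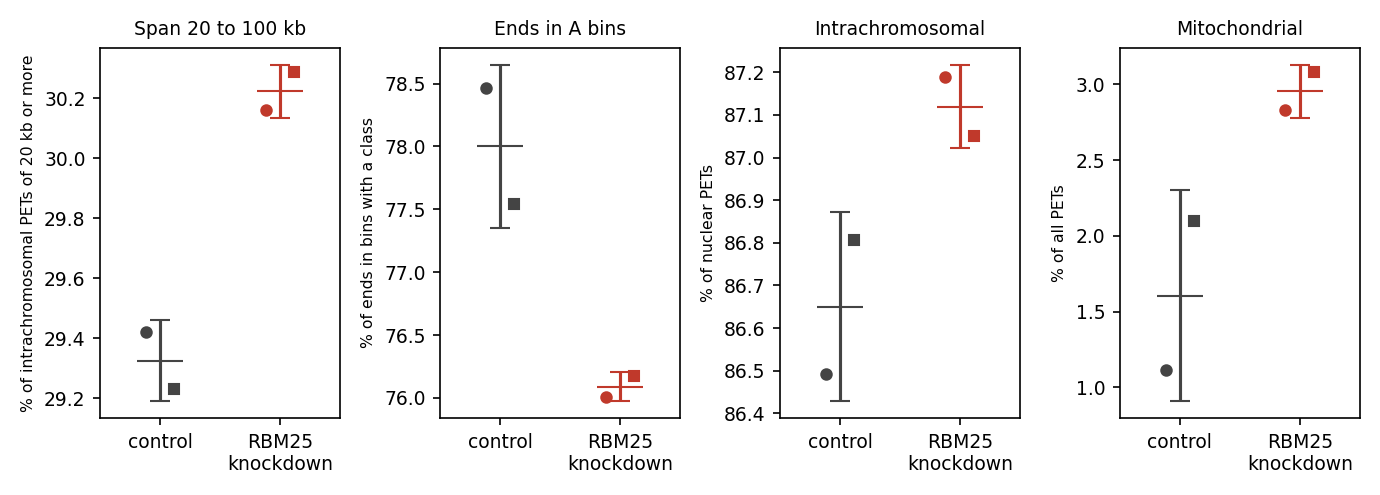
Share of PETs in each library, in percent, for 4 measures: spans of 20 to 100 kb among intrachromosomal PETs of 20 kb or more, ends in A bins, intrachromosomal PETs among nuclear PETs, and PETs with a mitochondrial anchor. Circles are replicate 1, squares replicate 2, horizontal lines group means and bars the SD (n = 2); in each panel both knockdown libraries lie on the same side of both controls, and the vertical axes do not start at 0.

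Intrachromosomal PETs made up 87.1% ± 0.0984 of nuclear PETs in knockdown libraries and 86.6% ± 0.222 in controls (SD, n = 2 each; exact permutation p = 0.333). With only pairs of 2 or more PETs the groups overlapped, at 99.427% ± 0.0477 and 99.411% ± 0.0268. The number of interactions called by the authors' model at a false discovery rate under 0.05 with 2 or more PETs followed depth. It was 943097 and 963003 in controls and 1100528 and 830075 in knockdown libraries, or 57438 ± 1748 and 55072 ± 2235 per 1000000 intrachromosomal PETs. Called pairs 20 kb or more apart overlapped by 28.5% of their union between the controls and by 29.2% between the knockdown libraries. The overlap between groups ranged from 27.4% to 29.8%. At a false discovery rate under 0.01 the number of called interactions did not follow depth. It was 619769 and 616070 in controls and 611494 and 482403 in knockdown libraries, lower in both (exact permutation p = 0.333).

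No loop passed the test between knockdown and control. Of the 5 loops with the smallest p in the direction of the knockdown, the first joined chromosome 22 from 30786251 to 30789112 with 30817103 to 30822201. It had 3.90 ± 0.414 PETs per 1000000 intrachromosomal PETs in knockdown libraries and 1.68 ± 0.265 in controls (SD, n = 2 each). Its log2 fold change was 1.20 (SE 0.25, adjusted p = 0.712 by edgeR). A loop on chromosome 17, from 8020877 to 8031955 and 8083993 to 8086114, had a log2 fold change of 2.11 (SE 0.46). Another on chromosome 6, from 26026688 to 26035729 and 26121800 to 26127697, had 1.98 (SE 0.46). The remaining 2 lay on chromosome 17, from 21359668 to 21361667 and 21413709 to 21417063, with 1.57 (SE 0.36), and on chromosome 5, from 58513804 to 58516472 and 58604656 to 58614340, with 1.66 (SE 0.40).

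In the direction of the control, a loop on chromosome 10 joined 73072056 to 73081160 with 73523603 to 73537487, a span of 454 kb. It had 0.200 ± 0.00890 PETs per 1000000 in knockdown libraries and 1.11 ± 0.248 in controls (SD, n = 2 each), a log2 fold change of -2.43 (SE 0.51). A loop on chromosome 22 from 24955402 to 24966878 and 24985165 to 24993166 had -1.88 (SE 0.41). The loop on chromosome 15 from 70354395 to 70358130 and 70375856 to 70382834 had -1.67 (SE 0.37). Loops on chromosome 10, from 126235681 to 126250408 and 126286395 to 126296260, and on chromosome 1, from 228532504 to 228553918 and 228605105 to 228616388, had -2.34 (SE 0.52) and -1.61 (SE 0.37). The former had 31 and 13 PETs in the controls, and its log2 fold change was -1.48 without control replicate 1 and -2.92 without control replicate 2. All 10 had an adjusted p of 0.712 by edgeR. Of 42200 loops, 2809 had an unadjusted p under 0.05 by edgeR and 240 by DESeq2, and neither tool called any. The median tested loop had a mean count of 13, at which a 2-fold change was mostly not detectable.

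Loops grouped by span or compartment had medians near 0. The median log2 fold change was 0.00 for 32082 loops of 20 to 100 kb, -0.01 for 10052 loops of 100 kb to 1 Mb and -0.09 for 66 loops over 1 Mb. It was -0.01 for 36881 loops within A, 0.00 for 4860 within B and 0.05 for 452 between A and B. The difference between loops over 1 Mb and those of 20 to 100 kb was -0.09, and it was -0.11 and 0.08 when the libraries were split so that each side held 1 control and 1 knockdown library. It ran from -0.289 to -0.0807 with a library left out. With offsets for the totals of the 2 regions the medians of these classes were -0.24 and 0.03.

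Contacts between 100 kb bins that were called higher in knockdown libraries lay mostly within B. Of 132044 bin pairs, 99 were higher and 5 lower in knockdown libraries at an adjusted p under 0.05 by edgeR. B with B pairs made up 20.8% of the pairs tested and 70 of the 99 higher ones, and 78 of the 99 were adjacent bins. The neighbouring bins of chromosome 8 from 50900001 to 51000000 and 51000001 to 51100000 held 6.51 ± 0.180 PETs per 1000000 in knockdown libraries and 1.94 ± 0.977 in controls (SD, n = 2 each). Their log2 fold change was 1.78 (SE 0.25, adjusted p = 0.00377 by edgeR). Adjacent bins on chromosome 3, from 87400001 to 87500000 and 87500001 to 87600000, rose by 1.69 (SE 0.24, adjusted p = 0.00402 by edgeR). Those on chromosome 21, from 31800001 to 31900000 and 31900001 to 32000000, rose by 1.99 (SE 0.30, adjusted p = 0.00571 by edgeR). On chromosome 1, 219200001 to 219300000 and 219300001 to 219400000 rose by 1.87 (SE 0.29, adjusted p = 0.00980 by edgeR). On chromosome 2, 143400001 to 143500000 and 143500001 to 143600000 rose by 2.34 (SE 0.37, adjusted p = 0.0126 by edgeR). With offsets for the totals of the 2 regions, the first 4 of these 5 turned to -0.75, -0.33, -0.79 and -0.28, and the last was 0.36. Such a change of sign can come from the offsets, which subtract more than a rise shared by all contacts of both regions.

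The 5 bin pairs that fell were on chromosomes 16, 8, 7 and 2. Adjacent bins of chromosome 16 from 23500001 to 23600000 and 23600001 to 23700000 held 7.46 ± 0.803 PETs per 1000000 in knockdown libraries and 13.7 ± 0.702 in controls (SD, n = 2 each). Their log2 fold change was -0.82 (SE 0.15, adjusted p = 0.0314 by edgeR). Those of chromosome 8 from 48700001 to 48800000 and 48800001 to 48900000 had -0.88 (SE 0.17, adjusted p = 0.0372 by edgeR). On chromosome 7, bins from 61900001 to 62000000 and 62300001 to 62400000 had -2.77 (SE 0.57), and bins from 98400001 to 98500000 and 98500001 to 98600000 had -1.22 (SE 0.25), both with an adjusted p of 0.0479 by edgeR. On chromosome 2, bins from 3400001 to 3500000 and 3500001 to 3600000 had -1.07 (SE 0.22, adjusted p = 0.0485 by edgeR). Without control replicate 1, which held 36 and 116 PETs in the bin pairs of chromosome 7 against 12 and 70 in control replicate 2, the log2 fold changes of those 2 were -1.71 and -0.74 (adjusted p = 0.329 and 0.200), and the pair on chromosome 2 had an adjusted p of 0.0518. DESeq2 called 0 bin pairs, with 3222 at an unadjusted p under 0.05 against 15435 by edgeR, and so did edgeR with offsets for the totals of the 2 regions or with only pairs of 2 or more PETs. edgeR called 0 higher without knockdown replicate 1 or without knockdown replicate 2, and 401 and 4258 higher without control replicate 1 and control replicate 2.

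**Figure D2:**
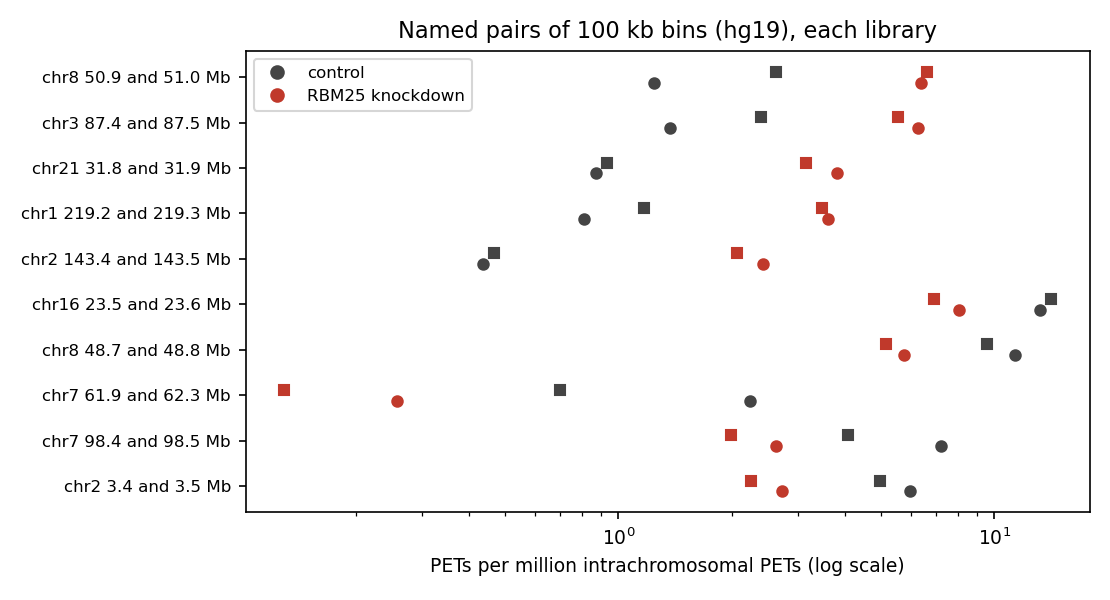
PETs per 1000000 intrachromosomal PETs, on a log axis, for the 10 named pairs of 100 kb bins, labelled by chromosome and the start of each bin in Mb. Circles are replicate 1 and squares replicate 2; in the upper 5 pairs both knockdown libraries lie above both controls, and in the lower 5 below.

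Across all bin pairs, the log2 fold change depended on distance and compartment. For adjacent bins the median was 0.34 in 7282 B with B pairs, 0.19 in 521 A with B pairs and 0.08 in 13449 A with A pairs. For bins 1.1 to 2 Mb apart it was -0.12, -0.15 and -0.21. Adjacent B bins exceeded adjacent A bins by a mean of 0.23 (SD 0.19 over chromosomes), above 0 in 20 of 23 chromosomes. Without chromosomes 13, 16, 17 and 22, whose eigenvector followed anchor density weakly, the mean was 0.29 (SD 0.15 over 19 chromosomes). With offsets for the totals of the 2 regions the excess over all chromosomes turned to -0.17 (SD 0.15), above 0 in 4 of 23, and the medians for adjacent bins were -0.12 within B and 0.06 within A. These offsets subtract more than a rise that all contacts of both regions share. The change of sign alone therefore does not show fewer contacts within B. With PETs between anchors present in all 4 libraries the excess was 0.0914 (SD 0.12), above 0 in 18 of 23. The change from adjacent to 1.1 to 2 Mb within A had the same sign in 23 of 23 chromosomes, with a mean difference of 0.28 (SD 0.06 over chromosomes), and it was 0.20 (SD 0.05) with the offsets for region totals. All chromosomes come from the same 4 libraries, so these counts and SDs do not measure the spread between libraries.

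**Figure D3:**
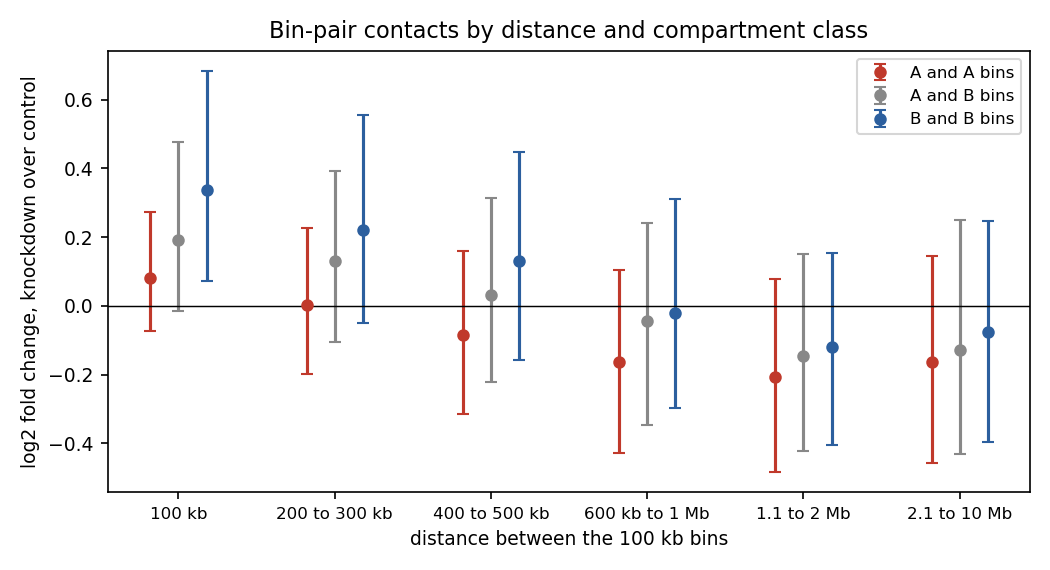
Log2 fold change of knockdown over control for pairs of 100 kb bins, by the distance between the bins and their compartment classes. Points are medians and bars the quartiles over bin pairs; adjacent B bins have the highest median, 0.34, and A bins 1.1 to 2 Mb apart the lowest, -0.21.

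Compartments differed in the share of contact ends they held. A bins held 76.1% ± 0.117 of ends in knockdown libraries and 78.0% ± 0.648 in controls (SD, n = 2 each; exact permutation p = 0.333). B bins held 37.3% ± 0.417 of anchors against 34.7% ± 1.69. Chromosome 4 took 2.40% ± 0.0221 of intrachromosomal PETs in knockdown libraries and 2.098% ± 0.330 in controls, and chromosome 13 took 2.36% ± 0.0144 against 2.08% ± 0.169. Chromosome 22 took 2.66% ± 0.00585 against 3.01% ± 0.306, and chromosome 17 took 4.86% ± 0.0194 against 5.27% ± 0.235. Without control replicate 1 these differences shrank, from 0.299 to 0.0657 percentage points for chromosome 4, from 0.278 to 0.158 for 13, from -0.347 to -0.130 for 22 and from -0.406 to -0.240 for 17, and from 2.63 to 1.43 for the anchors in B. The groups did not overlap in 21 of 23 chromosomes. Chance gives 33.3% for each, but chromosomes are not independent, since the shares sum to 100 and come from the same 4 libraries. In 21 of 23, control replicate 1 lay farther from the knockdown mean than control replicate 2.

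The compartment pattern itself was alike between the groups, with r = 0.968 between group means across 2597 bins of 1 Mb, which are not independent replicates. By group means, 1377 bins were A and 1068 were B in both groups, 96 were A in controls and B in knockdown libraries, and 56 the reverse. In 52 bins the sign split all 4 libraries by group. The smallest p was at chromosome 4 from 105000001 to 106000000, where the eigenvector was higher by 0.81 (SE 0.09, adjusted p = 0.404 by limma) in knockdown libraries. limma called 0 bins, with 250 at an unadjusted p under 0.05. Compartment strength was 3.37 ± 0.0201 in knockdown libraries and 3.54 ± 0.0785 in controls (SD, n = 2 each; exact permutation p = 0.333), but 2.93 ± 0.00527 against 2.87 ± 0.0197 after matrix balancing. Before balancing, mean observed over expected of B with B bins was 0.526 in knockdown libraries and 0.468 in controls. That was below A with B bins, at 0.685 and 0.658. After balancing it was above them, at 1.158 and 1.164 against 0.814 and 0.822. The strength before balancing therefore cannot be told apart from the totals of the bins.

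PETs across 50 kb bins were higher in knockdown libraries in B, by a median of 0.25 on the log2 scale (SD 0.31 over 12683 bins) and the median in A was -0.02 (SD 0.23 over 26930 bins). The score was not corrected for the totals of the regions, and no run with such offsets was made. This rise therefore cannot be told apart from the larger share of contact ends in B. The smallest p was at chromosome 1 from 74350001 to 74400000, where the score was higher by 1.31 (SE 0.09, adjusted p = 0.105 by limma). limma called 0 of 39625 bins, with 8853 at an unadjusted p under 0.05, of which 6878 were higher and 1975 lower. edgeR on the PET sums also called 0, with 10642, of which 5109 were higher and 5533 lower, so the excess of higher bins depended on the test and its scaling. With a library left out, 1 group keeps 1 library, which the test takes to vary like the other group. The knockdown libraries were more alike across bins (r = 0.992) than the controls (r = 0.970), so counts of calls from these fits are not given. The median difference over all bins was 0.0459, 0.0286 without control replicate 1 and 0.0588 without control replicate 2. It was 0.0475 and 0.0472 without knockdown replicates 1 and 2.

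Among pairs of chromosomes, contacts between 13 and 18 had the smallest p, with a log2 fold change of 0.17 (SE 0.04, adjusted p = 0.350 by edgeR). This pair holds 2 of the 10 pairs of 1 Mb bins with the most interchromosomal PETs, with 2457 and 1445 PETs, so its total is not only that of contacts spread over both chromosomes. The chromosome pair held 15852 and 17810 PETs in controls and 21390 and 16830 in knockdown libraries, so these bins alone were a small part. The excess ran beyond them. Along the side with the highest ratio, PETs outside these bins numbered 1354 and 2174 over all libraries. These were 34.6 and 29.7 times the numbers that the totals of the bins give. How much of the chromosome pair's total belongs to this wider excess was not tested. Unscaled, the former bin pair held 479 and 512 PETs in controls and 788 and 678 in knockdown libraries. The latter held 302 and 363 against 448 and 332. Contacts between chromosomes 9 and 17 followed with -0.12 (SE 0.03). edgeR called 0 of 253 chromosome pairs, with 34 at an unadjusted p under 0.05, and DESeq2 called 1 higher, with 21. Counts of calls with a library left out are not given, since 1 library of a group is then taken to vary like the other group. The median log2 fold change was -0.00918, -0.00686 without control replicate 1 and -0.0122 without control replicate 2. It was -0.00921 and -0.00637 without knockdown replicates 1 and 2.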

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

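PETs that join a mitochondrial and a nuclear anchor, which none of the contact tests used and which form most of the mitochondrial share in the figure of library values, made up 2.81% ± 0.162 of all PETs in knockdown libraries and 1.55% ± 0.670 in controls (SD, n = 2 each; exact permutation p = 0.333), above both controls in both libraries. The controls held 1.07% and 2.02%, so control replicate 1 stood apart, and the difference of 1.26 percentage points was 0.791 without it and 1.74 without control replicate 2. PETs between 2 mitochondrial anchors numbered 30013.5 ± 2016 in knockdown libraries and 11895 ± 6092 in controls.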

How the results depend on the processing

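Settings were planned before the data were examined, except offsets for the totals of the 2 regions, anchors present in all 4 libraries, matrix balancing, the run without chromosomes 13, 16, 17 and 22, edgeR on the PET sums, and pairs of 2 or more PETs together with leaving out pairs under 20 kb, which were chosen after seeing the data. The cause of a change was not tested unless stated.

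The 99 higher and 5 lower bin pairs became 0 and 0 with DESeq2, with offsets for the totals of the 2 regions and with pairs of 2 or more PETs. They became 250 and 10 with no filter on low counts, 939 and 55 with 250 kb bins, and 56 and 8 with anchors present in all 4 libraries. Of the 99, 59 had a value with those anchors, and their median log2 fold change fell from 1.36 to 1.03; over all 99 it fell from 1.79 to 0.086 with offsets for the totals of the 2 regions. The lower count was 9 with library size only and 3 with loess offsets over the mean count. Leaving out a library gave 0 to 4258 higher and 0 to 2224 lower; where a group keeps 1 library, that library is assumed to vary like the other group, and the knockdown libraries resembled each other more (r = 0.950) than the controls did (r = 0.931). Control replicate 2 resembled the knockdown libraries (r = 0.938 and 0.934) more than control replicate 1. With the replicate block, bin pairs became 1158 higher and 210 lower and loops 0 higher and 1 lower. Deviations of libraries with the same number had r = 0.00944 over bin pairs and 0.0135 over loops, so the numbers were not shown to pair the libraries.

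Adjacent B bins minus adjacent A bins turned from 0.23 (0.184 to 0.314 with a library left out) to -0.17 with offsets for the totals of the 2 regions, and A bins 100 kb apart minus A bins 1.1 to 2 Mb apart went from 0.28 (0.258 to 0.306) to 0.20. Of the named bin pairs, 5 changed sign with offsets for the totals of the 2 regions: -0.75, -0.33, -0.79 and -0.28 on chromosomes 8, 3, 21 and 1, and 0.37 on chromosome 8 from 48700001. These offsets can by themselves turn the sign of a rise or fall shared by all contacts of the 2 regions. With anchors present in all 4 libraries, 3 of the named bin pairs kept their call, 5 lost it and 2 had no value; the log2 fold change on chromosome 21 fell from 1.99 to 0.82. All 10 named bin pairs lost their call with DESeq2 and without either knockdown library, and 3 of the 5 lower ones also without control replicate 1. Adjusted p over the alternatives ran from 1.02e-11 to 0.860 for chromosome 8 from 50900001. The loop on chromosome 10 from 126235681 passed only with the replicate block (log2 fold change -2.39, adjusted p = 0.0383, range over its alternatives 0.0383 to 0.99999).

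Loops gave 0 calls except with no filter on low counts (1 higher and 2 lower), with the replicate block (1 lower) and leaving out a library (0 to 0 higher, 0 to 2 lower). Chromosome pairs gave 1 higher with DESeq2, and 0 to 70 higher and 0 to 86 lower when a library was left out. Insulation gave 0 to 10859 higher and 0 to 4241 lower on leaving out a library. Compartment bins gave 0 calls under each alternative, 0 to 0 on leaving out a library.

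Ranges in brackets are those of the first value when each library is left out. The knockdown minus control difference for 20 to 100 kb was 0.345 percentage points (0.227 to 0.463), 0.0639 with pairs of 2 or more PETs, 0.900 without pairs under 20 kb and 1.17 with both. For 100 kb to 1 Mb it was -0.745 (-0.939 to -0.551), and -0.452 without pairs under 20 kb. For 1 to 10 Mb it was -0.449 (-0.601 to -0.296), and -0.178 with pairs of 2 or more PETs. Over 10 Mb it was -0.147 (-0.318 to 0.0240), and under 20 kb 0.995 (0.360 to 1.63). The intrachromosomal share differed by 0.470 points (0.313 to 0.627), and by 0.0163 with pairs of 2 or more PETs, where the groups overlapped. The number of called interactions differed by 12252 (-122975 to 147478). At a false discovery rate under 0.01 it differed by -70971, from -135516.5 to -6425.5 with a library left out. Compartment strength differed by -0.164 (-0.220 to -0.109), by -0.248 in 500 kb bins, and turned to 0.0536 with matrix balancing and 0.0438 with matrix balancing and the same classes. Loops of 100 kb to 1 Mb minus those of 20 to 100 kb differed by -0.00138 (-0.0634 to 0.0329), and by -0.0767 with offsets for the totals of the 2 regions, and loops over 1 Mb by -0.0900 (-0.289 to -0.0807), and by -0.270 with those offsets.

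Promoter contacts, gene lists and their alternatives were not run, since positions of hg19 genes were not used here.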

Other observations

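Tests here were chosen after the result was seen, except that of interchromosomal ends in B and A bins, whose prediction was written before its value was computed. Intervals, SDs and counts over chromosomes describe the spread between chromosomes of the same 4 libraries, not the spread between libraries.

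The shift of contacts to B in the knockdown libraries also appeared in PETs that the bin pairs do not use. Interchromosomal ends were higher in B against A bins by 0.12 on the log2 scale (SD 0.10 over 23 chromosomes, above 0 in 20), beside 0.21 for intrachromosomal ends, which fits regions captured at different rates in the libraries. These ends lie in the same anchors as the bin pairs. B held 37.3% of anchors in knockdown libraries and 34.7% in controls. The value therefore cannot tell capture rates from anchor calling or from the knockdown. The controls differed from each other in the same regions: across 2597 bins of 1 Mb, the log2 ratio of control replicate 2 over 1 correlated with that of the knockdown mean over control replicate 2 at r = 0.314 (95% interval over chromosomes 0.211 to 0.392). Control replicate 2 stands in both ratios in opposite positions, which with no agreement gives r = -0.577 for libraries that vary alike. These libraries did not: the SD of the log2 ratio was 0.307 between the controls and 0.0631 between the knockdown libraries. The r with no agreement can therefore differ from -0.577 here. A difference between libraries not tied to the knockdown is a candidate source. With PETs between anchors present in all 4 libraries, adjacent B bins exceeded adjacent A bins by 0.0914 (95% interval over chromosomes 0.0377 to 0.140, above 0 in 18 of 23) against 0.23 (0.158 to 0.308), and the excess was smaller in 21 of 23. Anchors called in only some libraries cannot be told apart from other sources as the whole cause, because the interval holds both bounds set on what remains of the main value, 0.0584 and 0.117. An effect of the knockdown itself was not tested and stays open.

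The shorter contacts within A stayed with offsets for region totals and with anchors present in all 4 libraries. Adjacent A bins exceeded A bins 1.1 to 2 Mb apart by 0.28 (SD 0.06 over 23 chromosomes), by 0.20 (SD 0.05) with offsets for the totals of the 2 regions, and by 0.26 (SD 0.05) with anchors present in all 4 libraries. The offsets hold 1 term per bin, used alike for near and far pairs. They could change the difference only where the near and far pairs hold different bins, so capture rates are not excluded as a source. An anchor present in all 4 libraries is a merged region that overlaps an anchor of each. The extent called within it can still differ between libraries, so anchor calling is not excluded as a source. Control replicate 2 lay -0.191 percentage points from control replicate 1 in the share of 20 to 100 kb, against 0.900 between the groups, but a single pair of controls cannot exclude a difference between libraries not tied to the knockdown, and the 2 cannot be told apart. The knockdown stays open as untested.

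The 10 pairs of 1 Mb bins on different chromosomes with the most PETs had PETs in all 4 libraries. Neighbouring bins make them 6 junctions: 3 bin pairs join 9 with 13, 2 join 1 with 15, 2 join 13 with 18, and 1 each joins 1 with 19, 3 with 17 and 2 with 16. For each bin pair, either bin was moved 2 to 6 Mb in either direction, and the highest ratio of these 4 sides was kept. In 4 junctions, PETs along that side were over 3 times the number that the totals of the bins give, at least 13.3 times, which goes with rearranged chromosomes of the cell line. In 3, those of 1 with 19, 3 with 17 and 2 with 16, over 20% of PETs lay in 1 anchor pair, which goes with sequence shared by the 2 regions; in the other 3 the top anchor pair held at most 3.40%. The junction of 1 with 19 met both bounds, with 64.8% in 1 anchor pair and a ratio of 31.4. Those of 3 with 17 and 2 with 16 had ratios of 2.03 and 1.36, the latter from 1 PET. Since the junctions differ and the bounds were set after their values were seen, the 2 sources cannot be told apart for the set. By PET count the first bin pair joined chromosome 9 from 82000001 to 83000000 with chromosome 13 from 62000001 to 63000000, with 11931 PETs where the totals of the bins give 72.7, a ratio of 164; the highest ratio was 287, between chromosome 13 from 68000001 and chromosome 18 from 38000001. No biological explanation by group was tested.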
